A study of Mus musculus with 7 samples.

How the data were processed

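Total RNA from the terminal ileum of 7 male C57BL6J mice was extracted with a silica column kit, labelled with biotin and hybridised to Affymetrix mouse arrays, per the labels' protocols. The labels name 3 control samples and 4 low-dose penicillin samples as biological replicates, so the spread between arrays is a spread between mice. Litter and cage were not among the sample details used here. A litter or cage difference between the groups therefore cannot be told apart from penicillin. The deposited values are log2 expression values per probe set. They were made with RMA, a method that corrects background, equalises the arrays' distributions and summarises the probes of a set, and with the affy package, per the submitters' processing notes. Versions and a genome build are not given in the sources used here, so no coordinates are printed. The values lay between 2.50 and 14.7, and the median of each array lay between 5.43 and 5.45. RMA gives no detection call, so weakly expressed genes could not be told from background one by one.

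The deposited table held 45101 probe sets, of which 64 were the manufacturer's controls. Gene names came from the platform annotation of 2016, with symbols checked against a RefSeq gene table. In the annotation 34958 probe sets had 1 gene, 932 had several genes and 9211 had none listed. No gene was named from a probe set with several genes, and genes with no probe set of their own are not analysed here. The 34945 probe sets used stood for 18193 genes, and 34741 of them matched the RefSeq table by gene ID. Each gene was represented by the probe set with the highest mean over the 7 arrays. Genes whose mean was at or under the 25th percentile (log2 4.588) were left out, which left 13644 genes.

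Penicillin and control arrays were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes without a trend, two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Changes are given on the log2 scale as penicillin minus control with the standard error (SE) of the fit, and levels as mean ± SD. Every such value rests on 3 control and 4 penicillin mice. For 49 gene lists with 901 members, 811 of them on the array, the shift of the whole list against all other genes was tested with camera at a preset correlation of 0.01. The 48 lists with at least 3 tested members were adjusted together. The remaining list, of erythrocyte genes, had too few. Because genes of a list vary together, camera was also run with an estimated correlation, and fry was run to test whether the genes of a list moved, on balance, one way. Fry does not compare a list with other genes. The lists, the tests and the rule for naming genes were fixed before the data were examined.

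By that rule the text names the called genes, up to 10 with the largest rise and 10 with the largest fall. It names Reg3g, Reg3b, Saa1, Defb1, Pigr, Il17a, Slc10a2, Fabp6, Fgf15, Nr0b2 and Cd74 whatever their values. It also names up to 4 members of each list past camera, by the largest moderated t in the list's direction, and up to 2 of each other list described. Ikzf3, Ciita, Reg3a, Sdc1, Icam1, Abcc2, B3gnt7, Slc40a1, Car1, Aqp8, Slc26a3, Hoxb13, Hoxd10 and Hoxd13, and the genes of the scores described among the other observations, were chosen after their values were seen.

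The same fit was tested on simulated data in 20 runs of 13644 genes, 200 of them changed, with the spread and group sizes of this comparison. It recovered 66.1% of genes changed by log2 0.5, 93.8% of those changed by log2 1 and 98.8% of those changed by log2 2, with 4.98% false among the calls. A list shifted by log2 -0.5 was found in 20 of 20 runs. The simulated genes varied independently, which genes of a tissue do not. With 200 genes changed, the adjusted p threshold is also easier to reach than with the 13 calls of the real data. The recovered shares are therefore not the sensitivity of the real comparison. There Gzma, at -2.29, and Saa1, at -3.65, did not pass in limma (adjusted p = 0.0862 and 0.302). As alternatives, the values were quantile normalised again or centred on the array medians, and the filter was dropped or set at the 50th percentile. Probe sets of a gene were averaged, an intensity trend with a robust prior or array quality weights were used, and the replicate number was taken as a block. Each array was left out in turn, an unmoderated statistic and an adjusted p threshold of 0.1 were used, and lists were tested with fry, with ranks and with an estimated correlation. A gut segment score as a covariate, and a fit without control replicate 3 and penicillin replicate 3, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.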

Results

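Gene expression was measured in the terminal ileum, the last stretch of the small intestine, of male mice aged 8 weeks. In the penicillin group 4 mice had received penicillin at 6.7 mg/L from birth, a low dose. In the control group 3 mice had received no antibiotic. Weaning onto chow was at 4 weeks, and from 6 weeks all mice ate a diet with 45% of its energy from fat. The growth text of the labels speaks of livers, whereas the tissue label is terminal ileum. Fabp6, the bile acid carrier of ileal enterocytes, was among the strongest signals, at log2 14.4 ± 0.109 (SD, n = 3) in control mice and 14.5 ± 0.115 (SD, n = 4) in penicillin mice. Arrays correlated across probe sets with r between 0.992 and 0.998, and their number limits the precision of each value.

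The series asks how transcription in the ileum differs in mice given low-dose penicillin from birth. In penicillin mice the genes that load and carry antigen on MHC class II molecules fell together: Cd74, the invariant chain, fell by 1.56 ± 0.14 (SE, 2.94-fold) and H2-Aa, a class II alpha chain, fell by 1.14 ± 0.11 (SE, 2.21-fold). Genes of cytotoxic and intraepithelial lymphocytes fell as a group, with Ccl5, a T cell chemokine, down 2.53-fold and Itgae, the integrin that holds lymphocytes in the epithelium, down 1.57-fold. The immunoproteasome and class I loading list, the plasma cell list, the list of microbe-induced epithelial defence and the Paneth cell list were shifted lower as well. Enteroendocrine genes rose slightly as a group, by a median of 0.0775, with no single member past the threshold. The 7 list shifts named here passed camera and fry, with an adjusted p from 0.207 to 0.340 with an estimated correlation. For the count of lists higher in camera, chance could not be excluded, since 19 of 35 splits of the arrays gave as many. Ceacam10, a secreted member of the carcinoembryonic antigen family, had the largest fall of the called genes and fell by 3.15 ± 0.25 (SE, 8.90-fold).

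**Figure D1:**
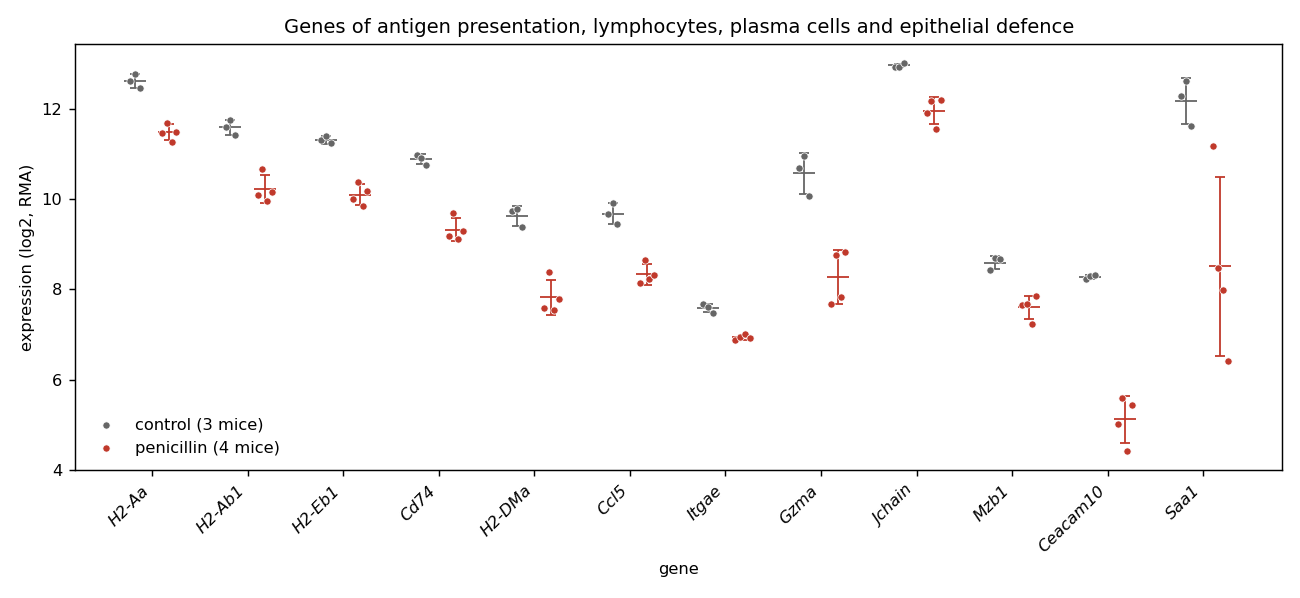
Expression on the log2 scale (vertical axis) of 12 genes (horizontal axis) in 3 control mice (grey) and 4 penicillin mice (red). Points are arrays and bars are mean ± SD. In each of the 12 genes every penicillin array lies below every control array, and Ceacam10 fell by 3.15.

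Of 13644 genes tested with limma, 12 were lower and 1 was higher in penicillin mice, and 9 of the 12 were lower at least 2-fold. Besides Cd74 and H2-Aa, the class II genes H2-DMa, H2-Ab1 and H2-Eb1 passed, with falls of 3.48-fold, 2.59-fold and 2.32-fold. Cd177, a surface glycoprotein known from neutrophils, fell by 1.45 ± 0.15 (SE, adjusted p = 0.0232). Slc9a3, the sodium-hydrogen exchanger of the brush border, fell by 1.08 ± 0.10 (SE, adjusted p = 0.0232). Nfkbiz, an inducible regulator of NF-kB, fell by 0.94 ± 0.11 (SE, adjusted p = 0.0443). Ikzf3, a lymphocyte transcription factor named after its value was seen, fell by 0.76 ± 0.092 (SE, adjusted p = 0.0481). The gene that rose was Pcdh19, a protocadherin, by 0.81 ± 0.073 (SE, adjusted p = 0.0232). Of the 3 probe sets of Ceacam10, 1 went the other way, at a mean of log2 3.44 near the bottom of the scale, and so did 1 of the 2 probe sets of Slc9a3, at log2 3.98. The other probe set of H2-DMa, at a mean of log2 6.41, differed by only -0.092. Of the 3 probe sets of Nfkbiz, 1, at log2 7.35, differed by only -0.13. All probe sets of H2-Aa and H2-Ab1 differed by -1.14 or below. In limma with probe sets averaged, H2-DMa, H2-Ab1 and Nfkbiz were not called (adjusted p = 0.0798, 0.0530 and 0.0726). Nor were Ikzf3, Slc9a3 and Pcdh19 called in that fit (adjusted p = 0.188, 0.0972 and 0.0644).

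At an unadjusted p under 0.05 there were 867 genes lower and 596 higher, where 682.2 in all would be expected by chance. With quantile normalisation of the deposited values the excess of lower genes was gone, at 694 lower and 707 higher, and with arrays centred on their medians there were 891 lower and 555 higher. The groups did not overlap in 10.34% of genes, where chance gives 5.714%. No gene passed in limma without control replicate 1, control replicate 2, penicillin replicate 1 or penicillin replicate 4, with 1223, 1985, 1282 and 1206 genes at an unadjusted p under 0.05. Without penicillin replicate 3 there were 2 calls, without control replicate 3 there were 8, of which 5 were among the 13, and without penicillin replicate 2 there were 15, of which 10 were among the 13. Over these 7 fits Slc9a3 was called in 0, Ceacam10 in 3 and Pcdh19 in 1. Cd74, H2-Aa and Cd177 were each called in 2. H2-DMa, H2-Ab1, H2-Eb1, Ccl5, Itgae, Nfkbiz and Ikzf3 were each called in 1. With the mean of probe sets 7 of the 13 were called. An unmoderated statistic called 0 genes and array quality weights called 774, the 13 included. Without control replicate 3 and penicillin replicate 3 together, an alternative added after seeing the data, 2 genes were lower and 0 higher, with 1440 at an unadjusted p under 0.05.

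Of the 48 gene lists, 15 were shifted lower and 7 higher in the camera test. With an estimated correlation no list passed, the smallest adjusted p being 0.2072, and 7 lists had an unadjusted p under 0.05. Fry passed 7 of the 22 lists: class II, class I, intraepithelial and cytotoxic lymphocytes, plasma cells, microbe-induced defence, Paneth cell products and enteroendocrine cells. The count of higher lists was 2 without control replicate 3, 4 without penicillin replicate 3, 4 without penicillin replicate 4 and 12 without control replicate 2.

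The MHC class II list fell by a median of 0.87 over 10 members (camera adjusted p = 4.9e-10; adjusted p = 0.207 with an estimated correlation). Over all genes 5 members passed, all lower, and 7 passed adjusted over the list alone, all lower. Of the members 9 had lower values. H2-DMa, which helps to load peptide, went from 9.63 ± 0.220 to 7.83 ± 0.391 (SD) and Cd74 from 10.9 ± 0.111 to 9.32 ± 0.255 (SD). Ciita, the master regulator of class II transcription, named after its value was seen, had a difference of -0.60 ± 0.15 (SE, adjusted p = 0.259 over all genes). In every mouse of the penicillin group the mean of the list was below that of every control mouse.

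The MHC class I list fell by a median of 0.39, and all 13 members had lower values (camera adjusted p = 2.1e-09; adjusted p = 0.319 with an estimated correlation). None passed over all genes, and 8 passed adjusted over the list alone, all lower. The immunoproteasome subunits Psmb8 and Psmb9 differed by -1.40 ± 0.22 and -1.11 ± 0.14 (SE), with adjusted p of 0.0911 and 0.0557 over all genes. Psmb10 differed by -0.53 ± 0.097 and Nlrc5, the regulator of class I transcription, by -1.17 ± 0.21 (SE). The interferon response list fell by a median of 0.18 over 29 members (camera adjusted p = 0.00106; adjusted p = 0.579 with an estimated correlation), and 7 members passed adjusted over the list alone, all lower, with 0 over all genes. Zbp1, Iigp1, Gbp6 and Irf1 differed by -1.11, -1.24, -1.10 and -0.51. The call was lost without control replicate 2 (adjusted p = 0.0524).

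The list of intraepithelial and cytotoxic lymphocytes fell by a median of 0.58 over 13 members (camera adjusted p = 1.3e-08; adjusted p = 0.207 with an estimated correlation). Over all genes 2 members passed, Ccl5 and Itgae, and 7 passed adjusted over the list alone, all lower. Gzma, granzyme A, went from 10.6 ± 0.450 in control mice to 8.27 ± 0.602 (SD) in penicillin mice, a 4.90-fold difference with an adjusted p of 0.0862 over all genes. Nkg7, a cytotoxic granule protein, differed by -1.0 ± 0.15 (SE). The T cell list fell by a median of 0.19 over 10 members (camera adjusted p = 0.0111; adjusted p = 0.579 with an estimated correlation). Of these 2 passed adjusted over the list alone and 0 over all genes. The 2 were Cd3g and Cd3d, CD3 chains of the T cell receptor complex, which differed by -1.29 and -0.59. That call was lost without control replicate 2 (median -0.13, adjusted p = 0.0999), without penicillin replicate 4 (adjusted p = 0.0618), with array quality weights (adjusted p = 0.367) and without control replicate 3 and penicillin replicate 3 together (adjusted p = 0.0725).

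The plasma cell and immunoglobulin list fell by a median of 0.48 over 13 members (camera adjusted p = 1.6e-05; adjusted p = 0.207 with an estimated correlation). None passed over all genes. Adjusted over the list alone 7 were lower and 1, Sdc1, was higher. Sdc1, named after its value was seen, differed by 0.31 ± 0.089 (SE) and is also made by epithelial cells. Jchain, which joins secreted IgA, went from 12.9 ± 0.038 to 11.9 ± 0.301 (SD), and Mzb1, an antibody secretion factor, differed by -0.99 ± 0.14 (SE). Irf4 and Eaf2 differed by -0.95 and -0.50. The B cell list did not pass (median -0.11, adjusted p = 0.0556), with Cd79b and Pou2af1 at -0.74 and -0.68. The macrophage and dendritic cell list fell by a median of 0.28 over 21 members, none of which passed over all genes or adjusted over the list alone (camera adjusted p = 1.1e-04; adjusted p = 0.594 with an estimated correlation). Itgax and Csf1r differed by -0.30 and -0.34. Without control replicate 3, whose mean over the list was the highest, the median was -0.16 (adjusted p = 0.0381). That call was lost with array quality weights (adjusted p = 0.171) and without control replicate 3 and penicillin replicate 3 together (adjusted p = 0.146).

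The list of epithelial defence genes known to respond to microbes fell by a median of 0.41 over 18 members (camera adjusted p = 6.2e-05; adjusted p = 0.207 with an estimated correlation). None passed over all genes, while 9 were lower and 1 higher adjusted over the list alone. Saa1, an acute-phase protein made by ileal epithelium, was at 12.2 ± 0.508 in control mice and 8.51 ± 1.98 (SD) in penicillin mice, where single mice ranged from 6.41 to 11.2. Its difference of -3.65 ± 0.97 (SE, 12.5-fold) had an adjusted p of 0.302. Retnlb, a goblet cell antibacterial protein, differed by -2.66 ± 0.69 (SE), and its control level was highest in control replicate 3, at 9.82 against 7.13 and 7.38. Defb1 differed by -1.18 ± 0.22 and Pigr, the receptor that carries IgA across the epithelium, by -0.34 ± 0.069 (SE). Among the C-type lectins Reg3g differed by -0.52 ± 0.17, Reg3b by -0.18 ± 0.094 and Reg3a, named after its value was seen, by 0.79 ± 0.19 (SE). Reg3b, at 14.2 to 14.5, and Reg3g, at 13.5 to 14.4, lay near the top of the arrays' scale, where differences can be compressed. Duoxa2, a maturation factor of an epithelial oxidase, differed by -0.79 ± 0.20 (SE).

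Paneth cell products fell by a median of 0.13, and all 7 members had lower values (camera adjusted p = 1.8e-04; adjusted p = 0.340 with an estimated correlation). Adjusted over the list alone 3 passed, Mptx1, Pla2g2a and Mmp7, and 0 over all genes. They differed by -1.09 ± 0.15, -0.62 ± 0.10 and -0.47 ± 0.10 (SE). The list of NF-kB and Toll-like receptor signalling fell by a median of 0.11 over 21 members (camera adjusted p = 0.0111; adjusted p = 0.258 with an estimated correlation). Nfkbiz passed over all genes, and 5 members were lower adjusted over the list alone: Nfkbiz, Tlr1, Tlr2, Tlr4 and Icam1, the last named after its value was seen. Tlr1, Tlr2 and Tlr4 differed by -0.85, -0.46 and -0.52, and Icam1 by -0.35. That call was lost without control replicate 2 (adjusted p = 0.125) and with the filter at the 50th percentile (adjusted p = 0.205). The Th17 and ILC3 list fell by a median of 0.10 over 11 members (camera adjusted p = 0.0273; adjusted p = 0.372 with an estimated correlation), with 1 member, Cxcr6, past adjusted over the list alone and 0 over all genes. Cxcr6 and Ltb differed by -0.49 and -0.34. The call was lost without control replicate 1, penicillin replicate 3 or penicillin replicate 4 (adjusted p = 0.0591, 0.0518 and 0.0868). It was also lost with no filter (adjusted p = 0.0969), with the filter at the 50th percentile (adjusted p = 0.451) and with array quality weights (adjusted p = 0.0593), and was kept in 11 of 20 settings. Il17a lay under the filter, at 4.476 in control mice and 4.455 in penicillin mice.

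**Figure D2:**
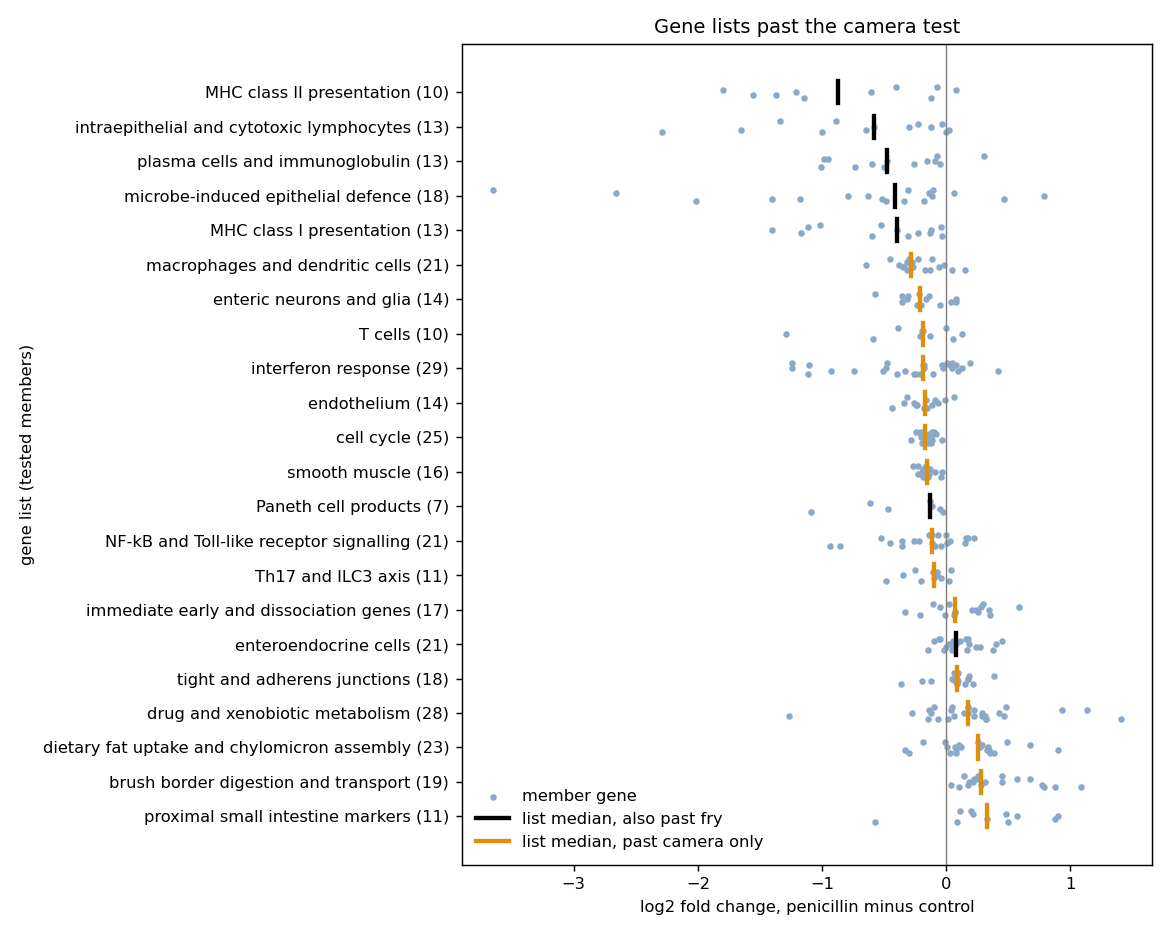
Log2 fold change of penicillin over control (horizontal axis) for the members (points) of the 22 lists past camera (vertical axis, with the number of tested members). Short vertical bars are list medians, black where fry passed too and orange where it did not. The class II list has the lowest median, at -0.87.

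Enteroendocrine genes, which mark the hormone-secreting cells of the epithelium, rose by a median of 0.077 over 21 members, 16 of which had higher values (camera adjusted p = 0.00459; adjusted p = 0.207 with an estimated correlation). None passed over all genes or adjusted over the list alone. Neurod1, Gip and Nts differed by 0.27, 0.40 and 0.45, and Nts by 0.26 without control replicate 3. The median was 0.13 without penicillin replicate 1 and 0.12 without penicillin replicate 4, and the call was lost with the filter at the 50th percentile (adjusted p = 0.0611). Genes of drug and xenobiotic metabolism rose by a median of 0.18 over 28 members (camera adjusted p = 7.3e-05; adjusted p = 0.340 with an estimated correlation), with 0 past either threshold for single genes. Cyp2d26 differed by 1.14 ± 0.25, Cyp2j6 by 0.48 ± 0.13 and Abcb1a, an efflux pump, by 0.47 ± 0.15 (SE), or 0.30 without control replicate 3. The tight and adherens junction list rose by a median of 0.087 over 18 members (camera adjusted p = 0.00268; adjusted p = 0.579 with an estimated correlation), with 0 past either threshold. Ocln and Tjp1 differed by 0.18 and 0.15, and the call was lost without control replicate 3 (median 0.046, adjusted p = 0.0861) and without control replicate 3 and penicillin replicate 3 together (adjusted p = 0.126).

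Control replicate 3 stood apart from the other 6 arrays. On the first principal component, which held 48.0% of the variance, it lay at -30.0, while the others lay between -2.90 and 17.6. Of 8 colon genes that were in no other list, 4 were highest there. Car1, a carbonic anhydrase of colonocytes, was at log2 14.1 there and between 5.11 and 10.8 elsewhere, and Aqp8 was at 8.27 against 3.86 to 4.29, while Slc26a3 was at 11.5 against 11.1 to 11.6. The mean score of the 8 genes was 1.35 in control replicate 3 and between -0.52 and 0.21 elsewhere, and without Car1 and Aqp8 it was 0.26 against -0.18 to 0.037. Its brush border list was at -0.92, against -8.4e-04 to 0.54 elsewhere, relative to the mean of the 7 arrays.

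Several lists of enterocyte and proliferation genes moved with that array. The brush border list rose by a median of 0.28 and all 19 members had higher values (camera adjusted p = 6.2e-05; adjusted p = 0.594 with an estimated correlation), with Treh and Slc15a1 at 1.08 ± 0.44 and 0.79 ± 0.35 (SE). Dietary fat uptake rose by a median of 0.25 over 23 members (camera adjusted p = 0.0151; adjusted p = 0.594 with an estimated correlation), with Apoa4 and Fabp2 at 0.90 and 0.27. Proximal small intestine markers rose by a median of 0.33 over 11 members (camera adjusted p = 0.0482; adjusted p = 0.594 with an estimated correlation). One of them, the iron exporter Slc40a1, named after its value was seen, was lower adjusted over the list alone, at -0.57. Immediate early genes rose by a median of 0.071 over 17 members (camera adjusted p = 0.0425; adjusted p = 0.594 with an estimated correlation), with Dusp1 at 0.35. The cell cycle list fell by a median of 0.17 and all 25 members had lower values (camera adjusted p = 0.00157; adjusted p = 0.682 with an estimated correlation), with Top2a at -0.28. No member of these 5 lists passed over all genes. Without control replicate 3 the adjusted p of these lists was 0.654, 0.894, 0.607, 0.858 and 0.916 in the order given, and the medians were 0.0029, 0.0023, 0.15, -0.053 and -0.0037. Treh, Slc15a1, Fabp2 and Top2a then differed by 0.49, 0.34, 0.17 and -0.15. The brush border median was 0.47, 0.49 and 0.18 without control replicate 1, control replicate 2 and penicillin replicate 3, and the cell cycle median -0.26 and -0.11 without control replicate 1 and penicillin replicate 3. The immediate early median was 0.20, 0.26 and 0.17 without control replicate 1, control replicate 2 and penicillin replicate 1, and the proximal median 0.56 without penicillin replicate 1. The fat uptake, proximal and immediate early lists also lost their calls without penicillin replicate 3 (medians 0.17, 0.21 and 0.12, adjusted p = 0.0518, 0.0651 and 0.143) and without penicillin replicate 4 (medians 0.098, 0.20 and 0.12, adjusted p = 0.104, 0.253 and 0.0681). Array quality weights, the colon gene score as a covariate, and the fit without control replicate 3 and penicillin replicate 3 together each ended all 5 calls. Of 20 settings the calls were kept in 14, 11, 8, 10 and 14, in the order given.

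**Figure D3:**
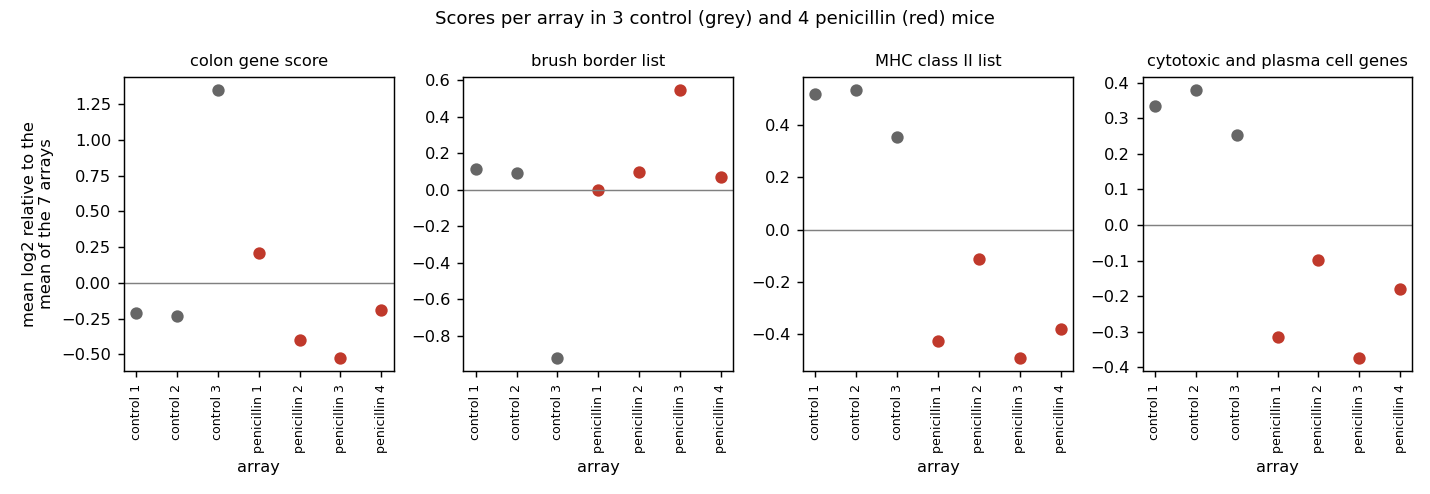
Mean log2 value relative to the mean of the 7 arrays (vertical axis) in each array (horizontal axis, control grey, penicillin red) for the colon gene score, the brush border list, the class II list, and the cytotoxic and plasma cell genes. Control replicate 3 lies apart in the first panel, at 1.35, and in the second, at -0.92, while in the last 2 panels the groups do not overlap.

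Of 4 lists of the tissue under the epithelium, 3 were lower. The smooth muscle list fell by a median of 0.16 and all 16 members had lower values (camera adjusted p = 0.0128; adjusted p = 0.674 with an estimated correlation), with Myocd at -0.27. Enteric neurons and glia fell by a median of 0.21 over 14 members (camera adjusted p = 0.0127; adjusted p = 0.594 with an estimated correlation), with the neuropeptide Vip at -0.57. Endothelial genes fell by a median of 0.17 over 14 members (camera adjusted p = 0.00433; adjusted p = 0.594 with an estimated correlation), with 1 member, Emcn at -0.44, past adjusted over the list alone. No member of these 3 lists passed over all genes. The muscle and nerve calls were lost without control replicate 1 (medians -0.065 and -0.068, adjusted p = 0.376 and 0.313) and without penicillin replicate 4 (medians -0.081 and -0.13, adjusted p = 0.288 and 0.18), and the endothelial call without control replicate 3 (median -0.074, adjusted p = 0.152). Without control replicate 2 the muscle and nerve medians were -0.25 and -0.33. Without control replicate 3 and penicillin replicate 3 together the nerve call (adjusted p = 0.0659) and the endothelial call (adjusted p = 0.553) were lost, as they were with the filter at the 50th percentile (adjusted p = 0.0633 and 0.157). The nerve call was also lost with the mean of probe sets (adjusted p = 0.0665), and the endothelial call with the colon gene score as a covariate (adjusted p = 0.279). The list of fibroblasts and extracellular matrix did not pass (median -0.085, adjusted p = 0.374). Without control replicate 3 and penicillin replicate 3 together its median was 0.16, higher in penicillin mice (camera adjusted p = 5.3e-04).

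Bile acid genes did not shift as a list (median 0.095 over 11 members, adjusted p = 0.297). Adjusted over the list alone 2 members were higher and 1 lower, with 0 over all genes. Slc10a2, the ileal bile acid importer, differed by 0.82 ± 0.23 (SE), Abcc2, named after its value was seen, by 1.10, and Abcc3, a basolateral exporter, by -0.49 ± 0.083 (SE). Without control replicate 3, where Slc10a2 was at 9.91 and lower than in the other control mice, Slc10a2 differed by 0.51 and Abcc2 by 0.67. Fgf15, the ileal hormone that represses bile acid synthesis, was at 8.62 ± 1.02 and 7.48 ± 0.836 (SD), and Nr0b2 at 5.20 ± 0.302 and 5.25 ± 0.151 (SD). Fgf15 differed by -1.14 ± 0.57 (SE, adjusted p = 0.508), and by -0.73 without control replicate 2. Penicillin replicate 4 was at 8.73 and the other 3 penicillin mice at 6.97 to 7.13, with control mice at 7.49, 8.93 and 9.45. Nr0b2 differed by 0.056 ± 0.15 (SE, adjusted p = 0.889), a difference that turned to -0.041 without control replicate 3.

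The other lists did not pass camera. The adjusted p was 0.0604 for cholesterol synthesis, 0.0604 for retinoid metabolism, 0.0686 for colon markers, 0.0932 for the circadian clock, 0.144 for distal ileum markers and 0.151 for the Th1 axis. It was 0.163 for oxidative phosphorylation, 0.191 for adipocytes, 0.200 for pancreatic acinar cells, 0.206 for follicle-associated epithelium and Peyer's patch organisers, 0.287 for hepatocytes and 0.339 for regulatory T cells. It was 0.374 for stem and crypt base cells and for the endoplasmic reticulum stress response, 0.401 for goblet cells, 0.518 for mast cells and eosinophils and 0.519 for aryl hydrocarbon receptor targets. For glucocorticoid targets, fatty acid synthesis, carbohydrate metabolism, neutrophils, PPAR alpha targets and tuft cells it was 0.614, 0.645, 0.873, 0.934, 0.934 and 0.970. The median and the direction of the test differed in sign for glucocorticoid targets, neutrophils and PPAR alpha targets, and the median and mean for carbohydrate metabolism. Muc2, the main goblet cell mucin, was at 13.4 ± 0.110 and 13.2 ± 0.111 (SD).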

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

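Of 91 genes and 48 list means checked in the 4 penicillin arrays, 12 had 1 array whose distance from its nearest neighbour took up a larger part of the group's range than Dixon's 95% critical value for 4 samples. Chance alone gives this in about 1 of 20 groups. Penicillin replicate 2 was the highest of its group, on the log2 scale, for Psmb9 (9.28, others 8.77 to 8.79), Psmb8 (9.80, others 8.89 to 8.99), Psmb10 (11.5, others 11.2 to 11.3) and Ciita (5.59, others 5.12 to 5.19). Penicillin replicate 4 was the highest for Fgf15 (8.73, others 6.97 to 7.13), Nr0b2 (5.48, others 5.15 to 5.20), Elovl6 (9.78, others 9.60 to 9.63) and Ascl2 (7.31, others 7.07 to 7.09). Penicillin replicate 3 was the highest for the peptide transporter Slc15a1 (10.7, others 9.93 to 10.1). It was the lowest, relative to the control mean, for the means of the follicle-associated epithelium list (-0.31, others -0.071 to -0.040) and of the neutrophil list (-0.27, others -0.041 to -0.0086). Penicillin replicate 1 was the lowest for Apoa4 (9.96, others 11.5 to 11.6). No explanation was tested for these values.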

How the results depend on the processing

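The gut segment covariate and the fit without control 3 and penicillin 3 were chosen after seeing the data. Array quality weights called 488 genes lower and 286 higher, the 0.1 threshold 37 and 3, the segment covariate 31 and 4 and the mean of probe sets 7 and 0. The unmoderated statistic called 0 and 0 (1238 genes at an unadjusted p under 0.05), and the fit without control 3 and penicillin 3 called 2 and 0. Over the fits that leave out 1 array the counts ran from 0 to 14 lower and from 0 to 1 higher. Quantile normalisation, median centring, both filters and the trend gave 10 to 13 lower and 1 higher. The 13 called genes kept their sign in every setting that tested them, and all 13 were called with the segment covariate and with array weights. Genes called for so clear a separation of the groups could hardly turn sign. Array weights called 774 genes in all, so neither the kept sign nor that setting tests the 13. The replicate numbers did not pair the mice (r of deviations -0.16, 0.0030 and -0.42), and not every array correlated best with its own number. A replicate block called 0 genes in each direction (803 at an unadjusted p under 0.05), and 5 lists higher and 15 lower. It ended the calls of fat uptake, proximal markers, NF-kB, Th17 and smooth muscle. Penicillin replicate 4 has no control of its number, so it added nothing to the difference in that fit. The medians of fat uptake and smooth muscle, 0.098 and -0.081, were those without penicillin replicate 4. Of these calls, all but NF-kB were also lost without that array. Lists higher numbered 3 with array weights, 1 with fry, 0 with an estimated correlation, 4 with the segment covariate and 4 without control 3 and penicillin 3, and from 2 to 12 with 1 array left out. Lists lower numbered 6 with fry and 0 with an estimated correlation, and from 12 to 17 with 1 array left out. The class II, class I, cytotoxic, plasma cell, defence and Paneth lists lost their calls only with an estimated correlation, and the enteroendocrine list also with the 50th percentile filter. Where fewer arrays or members entered, that alone widens the error; otherwise the cause was not tested. Signal near the bottom of the scale limits weak genes.

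Among lists and named genes these differences turned sign. Of them 2 passed the threshold in the new direction, both without control 3 and penicillin 3: fibroblasts, higher (adjusted p = 5.3e-04), and cholesterol synthesis, lower (adjusted p = 0.0334). With the segment covariate they were 0.012 for Adipoq, -0.030 for Nr0b2, 0.047 for adipocytes, -0.0028 for aryl hydrocarbon receptor targets, -0.030 for bile acids, -0.034 for cholesterol synthesis, -0.0019 for fat uptake, -0.026 for distal ileum, 0.038 for fatty acid synthesis, 0.078 for fibroblasts, 0.020 for glucocorticoid targets, 0.013 for mast cells, 0.0054 for neutrophils and 0.0064 for tuft cells. Without control 3 and penicillin 3 they were 0.061 for Adipoq, -0.017 for Nr0b2, 0.073 for adipocytes, -0.040 for bile acids, -0.047 for brush border, 0.046 for cell cycle, -0.040 for cholesterol synthesis, -0.027 for the clock, 0.0094 for colon markers, -0.023 for fat uptake, -0.065 for distal ileum, 0.039 for fatty acid synthesis, 0.16 for fibroblasts, 0.032 for glucocorticoid targets and 0.014 for mast cells. The replicate block gave -0.018 for Nr0b2, -0.019 for aryl hydrocarbon receptor targets and -0.028 for retinoids. Array weights gave -0.0078 for aryl hydrocarbon receptor targets, 0.038 for cell cycle, -0.084 for cholesterol synthesis, -0.027 for distal ileum, 0.037 for fatty acid synthesis, 0.053 for fibroblasts and 0.11 for neutrophils. The 50th percentile filter gave -0.0011 for carbohydrate metabolism, 0.021 for fatty acid synthesis, 0.010 for glucocorticoid targets, -0.37 for hepatocytes, -0.0011 for stem cells and -0.095 for acinar cells. Fatty acid synthesis and glucocorticoid targets were at 0.0021 and 0.015 with quantile normalisation and at 0.0055 and 0.044 with the mean of probe sets, and neutrophils at 0.018 without a filter. With 1 array left out the range was -0.69 to 0.011 for Adipoq, -0.041 to 0.23 for Nr0b2, -0.44 to 0.046 for adipocytes, -0.019 to 0.063 for aryl hydrocarbon receptor targets, -0.047 to 0.23 for bile acids, -0.0041 to 0.15 for carbohydrate metabolism and -0.044 to 0.14 for cholesterol synthesis. It was -0.047 to 0.23 for distal ileum, -0.13 to 0.089 for fatty acid synthesis, -0.16 to 0.054 for fibroblasts, -0.045 to 0.028 for glucocorticoid targets, -0.053 to 0.26 for immediate early genes and -0.026 to 0.037 for stem cells. It was -0.27 to 0.0069 for mast cells, -0.055 to 0.017 for PPAR alpha targets, -0.028 to 0.13 for retinoids and -0.039 to 0.014 for tuft cells.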

Other observations

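The tests of single genes and the counts over other splits of the arrays were planned. The tests of the gut segment, of macrophage and stromal genes, of crypt genes, of the interferon gene sets and of probe sets without a single gene name were chosen after the results had been seen. Some lists that did not pass as a whole held members past the threshold adjusted over the list alone, none of them past it over all genes. In the retinoid list these were Rdh7 and Lrat, an enzyme that stores vitamin A as ester, higher by 1.68 ± 0.40 and 0.75 ± 0.18 (SE). In the carbohydrate list they were the glycolytic regulators Pfkfb3 and Hk2, at -1.22 ± 0.24 and -0.92 ± 0.19 (SE), and 1 of the 2 probe sets of Pfkfb3 went the other way. In the Th1 list they were the chemokine Cxcl9 and Stat4, at -0.98 ± 0.22 and -0.26 ± 0.054 (SE). Tnfaip2 in the follicle-associated list was at -0.49 ± 0.081 and Serpina1b in the hepatocyte list at 0.61 ± 0.12 (SE). In the colon list 3 were lower, Saa1, Retnlb and B3gnt7, the last at -0.25. Among 4087 tested probe sets with no gene or several genes listed, 4 were lower and 0 higher, with 243 lower and 163 higher at an unadjusted p under 0.05.

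Of lists without a call, 5 further genes are named by the rule, and none passed over all genes or adjusted over the list alone. The fat cell hormone Adipoq was at 11.9 ± 0.773 in control mice and 11.5 ± 0.347 (SD) in penicillin mice, and was highest in control replicate 3, at 12.8. It differed by -0.43, by 0.011 without control replicate 3 and by -0.69 without control replicate 1. Angptl4, a PPAR target that inhibits lipoprotein lipase, differed by 0.54 ± 0.15, Elovl6 by -0.31 ± 0.074, Ascl2 by 0.28 ± 0.082 and the clock gene Ciart by 0.37 ± 0.096 (SE). In these last 4 genes the groups did not overlap, as in 10.34% of all genes tested and 5.714% by chance. They were picked for a large moderated t, which makes a lack of overlap likely. Their adjusted p in limma over all genes was 0.308, 0.259, 0.334 and 0.295.

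The 7 arrays can be split into 3 and 4 in 35 ways. For the genes, 1 of 35 splits, the real one, gave as many as 12 lower, and 1 of 35 gave as many as 1 higher. The highest of the other splits was 0 in both directions, so chance can be excluded at a share of 0.05 for the lower count. This holds for the count over all 7 arrays and not for each gene. The splits treat the mice as independent, and a litter or cage shared within a group could not be tested. With 1 array left out the lower count ran from 0 to 14. Ceacam10 was called in 3 of those 7 fits and the other lower genes in fewer. The higher count is a single gene, Pcdh19, which was not called in 6 of the 7 fits that left out 1 array or with the mean of probe sets (adjusted p = 0.0644), so little can be drawn from its split count. For the lists lower, the real split gave 15 and 1 of 35 gave as many, the highest other being 13. With the direction not fixed, other splits reached 15. Penicillin replicates 1, 3 and 4 as the group of 3 gave 16 lists higher, and so did replicates 2, 3 and 4. Chance can therefore be excluded at a share of 0.05 only if the lower direction is taken alone. For the lists higher, 19 of the 35 splits gave as many as the real 7, and the highest other gave 16, so chance cannot be excluded.

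The class II genes fell in penicillin mice. The colon gene score, which rests mostly on Car1 and Aqp8 in control replicate 3, does not measure position within the ileum. A difference in that position therefore stays open. A difference in colon gene content is argued against as the whole cause. The mean of the list differed by -0.82, and by -0.88 ± 0.12 (SE) with the colon gene score as a covariate. Fewer macrophages are argued against as the whole cause as well, since the class II list fell further than 10 genes of the macrophage list with means over log2 7, by -0.55 (exact permutation p = 0.0286, two-sided, the smallest that 35 splits can give). Those 10 genes differed by -0.28 (exact permutation p = 0.0857). The class II list was chosen for its large fall after the results were seen, which makes a small p in that comparison more likely. A loss of B cells or of a class of dendritic cells, whose own genes were weakly measured, stays open. Lower class II expression per cell, in epithelium or immune cells of mice given penicillin, may contribute and was not tested.

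The 26 cytotoxic and plasma cell genes fell by 0.56 on average. Position within the ileum was not measured here either and stays open. With the colon gene score as a covariate the difference was -0.60 ± 0.092 (SE), which argues against colon gene content as the whole cause. An even loss of the muscle, nerve, fibroblast and endothelial tissue under the epithelium is argued against as the whole cause too. The cytotoxic and plasma cell genes fell further than 61 muscle, nerve, fibroblast and endothelial genes, by -0.41 (exact permutation p = 0.0286, two-sided). The latter differed by -0.15 (exact permutation p = 0.171). Intraepithelial lymphocytes lie within the epithelium, so for their genes this comparison does not bear on the tissue under it. A loss of only the layer next to the epithelium was not measured and stays open. The cytotoxic and plasma cell lists were also chosen for their falls, which makes a small p in that comparison more likely. Fewer lymphocytes and plasma cells in the ileum of penicillin mice is a hypothesis that these data leave open, beside lower expression per cell.

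Control replicate 3 stood apart. A more distal piece of gut in that sample is consistent with its colon gene score, 1.14 above the highest other array while the other 6 spanned 0.73, and with its brush border list 0.92 below the lowest other. Relative to the control mean, its distal ileum list was the lowest of the arrays, at -0.47 (others 0.026 to 0.25). Its adipocyte list was the highest, at 0.65 (others -0.58 to 0.089). The colon gene score rests mostly on Car1 and Aqp8. Of the 8 genes, 4 were highest in control replicate 3. Without Car1 and Aqp8 the score was 0.26 there and -0.18 to 0.037 elsewhere. The test could not have told colon from caecum, and the hindgut genes Hoxb13, Hoxd10 and Hoxd13 were near the bottom of the scale in every array, at 3.28, 3.70 and 4.30 in control replicate 3. More crypt and less villus could not be decided: cell cycle genes lay 0.36 above the highest other array, but the stem and crypt base list lay at -0.032 from the highest other, within the SD of 0.070 of the other arrays. No biological explanation was tested, since the design gives none for 1 control mouse.

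Within the interferon list, a hypothesis was that the GTPases induced by interferon gamma fell further than genes typical of type I interferon. The 7 GTPase genes differed by -0.88 (exact permutation p = 0.0286) and the 12 type I genes by -0.0064 (exact permutation p = 0.943). The difference between the sets was -0.87 (exact permutation p = 0.0571, two-sided), which misses the threshold and leaves the hypothesis open.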
